A study of Homo sapiens with 8 samples.

How the data were processed

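Genomic DNA of established human cell lines was bisulfite-converted and sequenced after hybrid selection of target regions, per the labels. The series held 8 libraries of 7 groups. MCF7 had 2 libraries, and MCF10A, MDA-MB-231, HCT116 and its DNMT1, DNMT3B and double knockout derivatives had 1 library each. Per the labels' protocols, libraries were made with methylated adaptors and an Illumina genomic library kit.

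The authors deposited 1 table per library, with 1 row per CpG that gives its position, a count and a fraction. The deposited count is the number of reads that cover the CpG, without normalization. The deposited fraction is the share of those reads that were methylated, to 3 decimals, and the header of the breast files calls it a methylation level. Reads had been mapped to genome build hg18, per the submitters' processing notes, and the aligner, the methylation caller and their settings are not given in the sources used here. The lowest coverage in every file was 10 reads, so less covered CpGs had been left out before deposit. The product of count and fraction was a whole number, within the rounding of the fraction, for at least 99.98% of rows in each file, and it was used as the number of methylated reads.

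The 2 tissues' files differed in layout. The breast files gave intervals of 1 bp, all on 1 strand, while the colon files gave intervals of 2 bp with a strand. The colon files held some repeated positions, 3168 rows in HCT116 and 2010 to 2084 rows in the knockouts. Rows that repeated another exactly were dropped, and the other rows of a position were summed. Breast and colon libraries were not compared for called differences, since a difference in upstream processing would be confounded with tissue. Breast levels did serve to choose some sets of CpGs and clusters read in the colon lines, and those choices carry the same confound. Chromosomes 1 to 22 and X entered the comparisons. Mitochondrial CpGs were read separately, and chromosome Y and unplaced sequences were left out.

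Depth, as the median coverage of a CpG, ran from 35 reads in MCF10A to 168 reads in the DNMT3B knockout. Targeted libraries hold amplified copies of a limited number of molecules, with no molecular identifiers, so intervals computed from reads cover counting error only. The spread between the 2 MCF7 libraries gave an estimate. CpGs with a median coverage of 167 reads and a level of 20 to 80% varied like draws of 4.08 independent reads. Choosing CpGs by an intermediate level can favour those at which the libraries disagree, so this number may be too low for CpGs in general. A cluster of 10 to 14 CpGs varied like 15.3 independent reads, and a cluster of 50 or more CpGs like 86.5. The labels do not say whether the MCF7 libraries came from separate cultures, so this spread may be technical alone.

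No genome or annotation of build hg18 was used here, and the gene table at hand belongs to another build. Regions were therefore CpG clusters, defined as runs of measured CpGs at most 100 bp apart with at least 10 CpGs in every library compared. They are named by their coordinates, 1-based and in build hg18, without genes. The gene lists fixed beforehand (luminal and basal genes, genes reported as methylated in cancer and others) were not used here. The level of a cluster was the unweighted mean of its CpG levels. A cluster was called different when the levels differed by at least 25 percentage points and by more than the 99th percentile of the absolute difference between the MCF7 libraries, which was 32.2 points. For MCF7, both libraries had to pass in the same direction. No p-value was computed across clusters, because every other group has 1 library.

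Single CpGs were compared with a two-sided Fisher's exact test on methylated and unmethylated reads, with Benjamini-Hochberg adjustment within a comparison. A CpG was called at an adjusted p below 0.05 with a difference of at least 25 points, and for MCF7 in both libraries. This test compares libraries, not conditions, and the count between the MCF7 libraries serves as the level without a difference of line. The position of the X chromosome's median difference was described by its percentile among 10000 random lists of autosomal clusters of the same size, matched on mean level. Overlaps of called clusters were set beside the product expected of independent lists, over all clusters and within 10-point classes of the control's level. They were also set beside 100 simulated pairs of unchanged libraries against the shared control. The simulation took the control's level as true, which gives clusters read near the limits of the scale almost no spread, so its overlaps may be too low.

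The rule for regions named in the text was the 5 clusters with the largest rise and the 5 with the largest fall per comparison. The tests, samples, thresholds and this rule were fixed before the data were examined. The alternatives fixed then were a coverage minimum of 20, a difference of 40 points, thinning to the shallower library, autosomes only, levels from summed reads, leaving out either MCF7 library, for mean levels only CpGs measured in every library of the tissue and, for the double knockout, other choices of methylated CpGs. A coverage minimum of 5 was not run because the files start at 10, and windows around transcription start sites were not run for lack of an annotation. The size rule was recomputed from the MCF7 pair for a coverage minimum of 20, thinning, autosomes only, summed reads, a gap of 200 bp and clusters of at least 5 CpGs. It stayed at 32.2 points for the pair's own counts, for CpGs in all 4 libraries of a tissue and with 1 MCF7 library left out. The colon protocols name 2 media and do not make clear which of them each knockout had. Alternatives chosen after seeing the data were a cluster gap of 200 bp, clusters of at least 5 CpGs, an effective number of reads, for called clusters only CpGs measured in all 4 libraries of a tissue, CpGs chosen on the breast lines and the share of methylated reads.

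The code was tested on simulated data in which 200 clusters fell by a known amount and clusters varied like the MCF7 libraries. Falls of 40 points were recovered in 74.5% of changed clusters for the DNMT1 knockout comparison over 8779 clusters, and falls of 60 points in 100%, with false calls in 0.420% and 0.350% of unchanged clusters. For the comparison of MDA-MB-231 and MCF10A over 23994 clusters, the recovered shares were 79.5% and 99.5%, with false calls in 0.635% and 0.660% of unchanged clusters. For the DNMT3B knockout over 10483 clusters the recovered shares were 73.0% and 96.5%, with false calls in 0.379% and 0.331%. For the double knockout over 10981 clusters they were 71.5% and 98.0%, with false calls in 0.427% and 0.380%. The level of 1 library was taken as true, so clusters read at 0 or 100% got almost no spread. The real MCF7 pair passed the size rule at 1.00% of clusters, above every simulated share of false calls, so those shares may be too low. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.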

Results

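Methylation at CpG sites was measured by targeted bisulfite sequencing in 4 breast and 4 colon libraries. Bisulfite converts unmethylated cytosine and leaves methylated cytosine, so the share of unconverted reads at a CpG is its methylation level. MCF7 is an oestrogen receptor-positive breast cancer line, MDA-MB-231 an oestrogen receptor-negative breast cancer line, and MCF10A an immortalised, non-tumorigenic breast epithelial line. HCT116 is a colon cancer line, studied with derivatives labelled as knockouts of DNMT1, of DNMT3B or of both. DNMT1 copies methylation onto newly replicated DNA, and DNMT3B is an enzyme that methylates unmethylated DNA. MCF7 had 2 libraries and every other group 1, so only MCF7 values carry an SD. The deletions themselves, and any enzyme activity left in the knockout lines, cannot be checked from methylation calls.

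The 4 breast libraries covered between 907510 and 1082728 nuclear CpGs, at median coverages of 54 reads in MCF7 library 1, 39 in MCF7 library 2, 35 in MCF10A and 45 in MDA-MB-231. The colon libraries covered fewer CpGs more deeply. HCT116 had 533075 CpGs at a median of 139 reads, the DNMT1 knockout 418808 at 155, the DNMT3B knockout 477978 at 168 and the double knockout 602465 at 92.

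At single CpGs, exactly 0 or 100% was read at 68.2% of CpGs in the double knockout. In the other libraries the share was 76.0% to 81.9%. These levels may rest on few molecules. Between the MCF7 libraries, CpGs with a level of 20 to 80% varied like about 4.08 independent reads. That number does not cover CpGs outside this range, and the choice by level may have made it too low. The mean level was 34.7% ± 1.59 (SD, n = 2) in MCF7, 33.0% in MCF10A and 29.9% in MDA-MB-231. In the colon lines it was 40.9% in HCT116, 34.1% in the DNMT1 knockout, 40.4% in the DNMT3B knockout and 29.6% in the double knockout. These means run over different CpGs. Over the 128715 CpGs measured in all 4 colon libraries the means were 36.1% in HCT116, 21.2% in the DNMT1 knockout, 35.4% in the DNMT3B knockout and 16.8% in the double knockout, and over the 473117 CpGs shared by the breast libraries they were 25.7%, 23.1% and 21.1% in MCF7, MCF10A and MDA-MB-231. As shares of methylated reads, MCF7 stood at 23.7% ± 0.312 (SD, n = 2) and MCF10A at 23.8%. These shares had 95% Wilson intervals at most 0.0198 points wide, which cover counting error only.

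Grouped into clusters, most regions were unmethylated in every line. Of 19074 clusters measured in all breast libraries, between 61.1% and 63.8% lay at 20% methylation or under. Clusters at 80% or over made up 10.5% and 10.1% in the MCF7 libraries, 6.73% in MCF10A and 4.80% in MDA-MB-231. Of 4785 clusters measured in all colon libraries, 26.8% lay at 80% or over in HCT116 and 26.3% in the DNMT3B knockout, but 5.62% in the DNMT1 knockout and 2.63% in the double knockout. Clusters between 20 and 80% made up 8.32% in HCT116, 23.8% in the DNMT1 knockout and 20.8% in the double knockout.

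**Figure D1:**
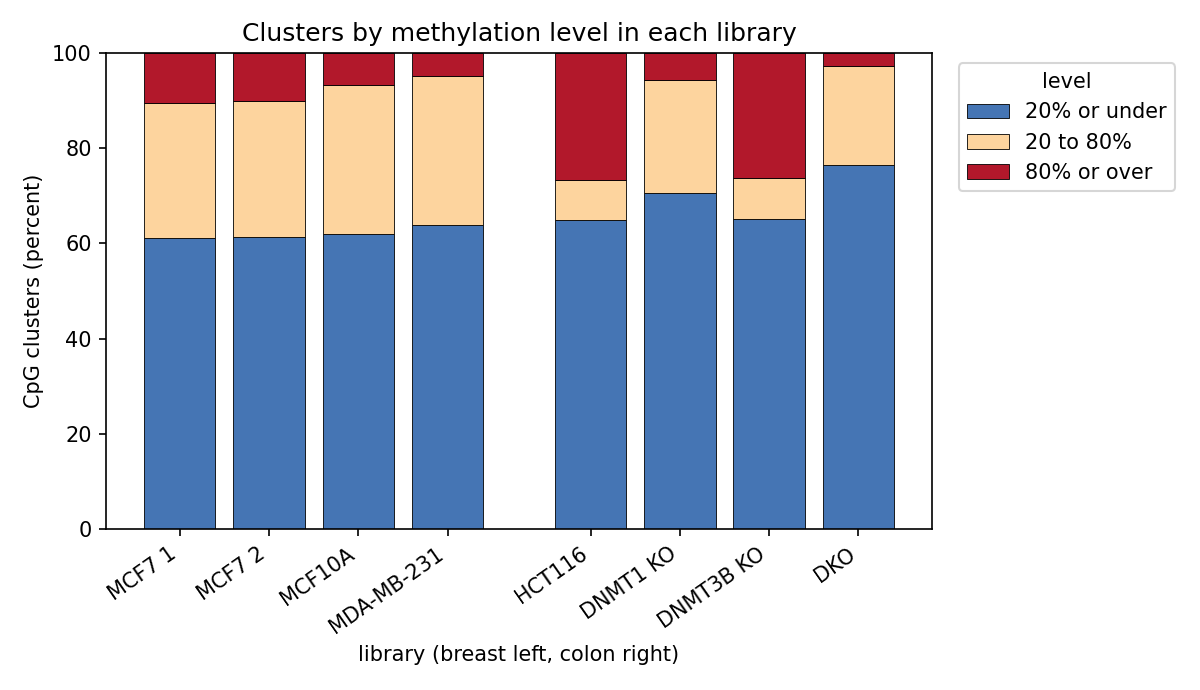
Percent of CpG clusters (vertical axis) at 20% methylation or under, between, and at 80% or over, for each library (horizontal axis), over 19074 clusters shared by the breast libraries and 4785 shared by the colon libraries. The class at 80% or over holds 26.8% of clusters in HCT116 and 2.63% in the double knockout.

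The 2 MCF7 libraries were compared first, to set the spread between libraries of 1 line. Cluster levels were close, with means of 29.7% and 29.4% over 22884 clusters and a median absolute difference of 1.30 points. The spread depended on the level: the SD between the libraries was 1.01 points for clusters at 5% or under, 9.51 points for those from 20 to 80% and 3.57 points for those at 95% or over. Across clusters, which are not independent replicates, Pearson's r was 0.972, and across 633770 single CpGs it was 0.866. The 99th percentile of the absolute difference, 32.2 points, became the size rule, so that 124 clusters higher and 105 lower in library 1 passed it by construction. Short clusters disagreed more often, 3.39% of those under 150 bp against 0.0830% of those of 300 bp or more.

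At single CpGs, Fisher's exact test called 42528 CpGs higher and 38051 lower in MCF7 library 1, or 12.7% of those tested, although both libraries came from 1 line. CpG counts therefore serve only beside this pair's share, and the comparisons rest on clusters. With reads reduced to the effective number that the MCF7 pair gives, no CpG passed in any of the 7 comparisons, an outcome fixed by that number and no evidence for or against a difference.

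MCF7 against MCF10A asks how an oestrogen receptor-positive cancer line differs from an immortalised epithelial line. Gains outnumbered losses: 1230 of 20521 clusters (5.99%) were higher in both MCF7 libraries and 518 (2.52%) were lower. Over the 19074 clusters measured in all breast libraries, 15959 could be called higher by their MCF10A level and 6296 lower. Of these, 1100 and 435 were called, so calls were about as frequent in both directions among clusters able to change. Of the 12472 clusters at 20% or under in MCF10A, 662 rose past the size rule, and their class as a whole went from a mean of 2.11% in MCF10A to 5.96% in MCF7. Losses lay mostly in clusters from 20 to 80% in MCF10A, of which 447 of 6424 were lower and 568 higher. Among 1625 clusters at 80% or over in MCF10A, 71 were lower and 53.6% were still at 80% or over in MCF7. Of clusters at 80% or over in 1 MCF7 library, 60.7% or 64.6% were at 80% or over in the other.

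The rise in MCF7 was nearly complete at several clusters. On chromosome 20, positions 61798711 to 61798801, 11 CpGs went from 0% in MCF10A, at 47.2 reads per CpG, to 96.8% ± 4.50 (SD, n = 2) in MCF7. A cluster of 26 CpGs on chromosome 8, positions 145719188 to 145719579, went from 0% to 93.5% ± 1.66. On chromosome 7, positions 2685509 to 2685628, the level was 2.64% in MCF10A and 98.7% ± 1.82 in MCF7, and on chromosome 2, positions 148317773 to 148317944, it was 0% and 96.6% ± 1.28. The reverse was seen on chromosome 8, where 23 CpGs at positions 38951300 to 38951510 read 96.7% in MCF10A and 0% in both MCF7 libraries, at 66.0 and 61.3 reads per CpG. A second cluster of that chromosome, positions 37674479 to 37674568, fell from 97.8% to 0.0541% ± 0.0765. On chromosome 2, 26 CpGs at positions 176703276 to 176703544 fell from 94.5% to 0.0169% ± 0.00442, and on chromosome 21, 46 CpGs at positions 37042140 to 37042458 fell from 91.8% to 0.235% ± 0.287.

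By chromosome, gains in MCF7 were most frequent on chromosome 20, with 67 of 694 clusters (9.65%), which also had the lowest autosomal share of losses, 9 clusters (1.30%). Losses were most frequent among autosomes on chromosome 8, with 33 of 817 clusters (4.04%). Shares by chromosome, here and below, run over all its clusters, whether or not their starting level allowed a call. Fisher's exact test on single CpGs called 46853 higher and 29320 lower of 541343, or 14.1% passing in both MCF7 libraries. With 1 MCF7 library in place of both, 1976 to 1977 clusters were higher (8.47% and 8.64%) and 709 to 730 lower (3.10% and 3.13%). At single CpGs, 80767 to 82708 were then higher (12.99% and 12.4% of those tested) and 50853 to 53824 lower (8.18% and 8.10%). Between the MCF7 libraries the shares of CpGs were 6.71% and 6.004%. At a difference of 40 points 342 clusters and 18151 CpGs were lower.

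MDA-MB-231 against MCF10A sets an oestrogen receptor-negative cancer line beside the epithelial line. Losses slightly outnumbered gains over all clusters, with 1510 of 23994 clusters (6.29%) lower and 1275 (5.31%) higher in MDA-MB-231. Over the 19074 clusters measured in all breast libraries, 1076 of the 6296 able to be called lower were lower. Of the 15959 able to be called higher, 881 were higher, so losses were clearly more frequent among clusters able to change. Gains came from unmethylated clusters, 779 of the 14102 at 20% or under in MCF10A, and from 496 intermediate ones. The losses took 1186 of 7703 intermediate clusters and 324 of 2189 clusters at 80% or over. Of the latter, 38.01% stayed at 80% or over in MDA-MB-231, against the 60.7% or 64.6% between the MCF7 libraries.

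Complete gains in MDA-MB-231 included 24 CpGs on chromosome 16, positions 29532244 to 29532398, at 0% in MCF10A with 96.2 reads per CpG and 100% in MDA-MB-231 with 44.9. On chromosome 9, positions 112381114 to 112381218, 12 CpGs read 0% and 100%, and on chromosome 5, positions 72779548 to 72779614, another 12 CpGs did so at 17.9 and 24.4 reads per CpG. Complete losses included 10 CpGs of chromosome X, positions 131179618 to 131179687, from 100% to 0%. On chromosome 3, positions 132563780 to 132563854, the level fell from 97.4% to 0%, and on chromosome 10, positions 31113849 to 31113987, 19 CpGs fell from 94.7% to 0%. The cluster at positions 103528806 to 103528987 of chromosome 10 fell from 94.4% to 1.27% over 18 CpGs. Chromosome 18 had the highest autosomal share of losses, 55 of 499 clusters (11.02%), and chromosome 20 the highest share of gains, 61 of 787 (7.75%).

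Fisher's exact test called 58536 CpGs higher and 76863 lower of 623049 between MDA-MB-231 and MCF10A, or 21.7%. Neither line has a second library. A difference of 40 points, in place of the size rule of 32.2 points, left 964 clusters lower.

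Many clusters differed from MCF10A in both cancer lines. Among 19074 clusters measured in all 4 breast libraries, 1100 were higher in MCF7 and 881 in MDA-MB-231, and 351 were higher in both. Independent lists of these sizes would share 50.8, or 125.7 if drawn within classes of 10 points of the MCF10A level, and simulated unchanged libraries against MCF10A shared 5.96 on average and 12 at most. Lower clusters numbered 435 and 1076, with 240 in both. Only the 6296 clusters at 32.2% or over in MCF10A can be called lower, so the 24.5 of independent lists over all clusters is too low, and within classes of level it was 75.3, with 4.36 in the simulation. MCF10A has 1 library and could not be split, so part of the excess may come from that shared library.

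The cancer lines were then compared with each other. MCF7 was more methylated than MDA-MB-231, with 1471 of 20667 clusters (7.12%) higher in both MCF7 libraries and 661 (3.20%) lower. Mean cluster levels were 27.9% and 23.3%. Of 1169 clusters at 80% or over in MDA-MB-231, 52.6% were also at 80% or over in MCF7, against the 60.7% or 64.6% between the MCF7 libraries, and of 13006 at 20% or under in MDA-MB-231, 883 were called higher in MCF7.

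Clusters with the largest rise towards MCF7 included 11 CpGs on chromosome 11, positions 18699359 to 18699518, at 0% in MDA-MB-231 and 99.3% ± 0.978 (SD, n = 2) in MCF7. On chromosome 3, 18 CpGs at positions 170868963 to 170869152 read 0% and 97.9% ± 1.25, and 11 CpGs at positions 32418159 to 32418287 read 0% and 96.0% ± 5.30. On chromosome 4, positions 25266394 to 25266539, the levels were 2.56% and 98.4% ± 2.29. In the other direction, the regions of chromosomes 5 and 16 that were fully methylated in MDA-MB-231 and unmethylated in MCF10A were also unmethylated in both MCF7 libraries. These were 14 CpGs of chromosome 5, positions 72779578 to 72779635, and 11 CpGs of chromosome 16, positions 29532240 to 29532353, each at 100% in MDA-MB-231 and 0% in MCF7. On chromosome 11, positions 72211105 to 72211256, the level was 96.8% in MDA-MB-231 and 1.44% ± 2.04 in MCF7.

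Chromosome 13 had the highest share of clusters higher in MCF7, 47 of 422 (11.1%). Fisher's exact test called 53279 CpGs higher and 26195 lower in MCF7 of 520658, or 15.3% passing in both MCF7 libraries. With a single MCF7 library, 2335 to 2364 clusters were higher, and 89137 to 90564 CpGs were higher (15.1% and 14.6% of those tested) and 42876 to 46115 lower (7.24% and 7.46%), against 6.71% and 6.004% between the MCF7 libraries.

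**Figure D2:**
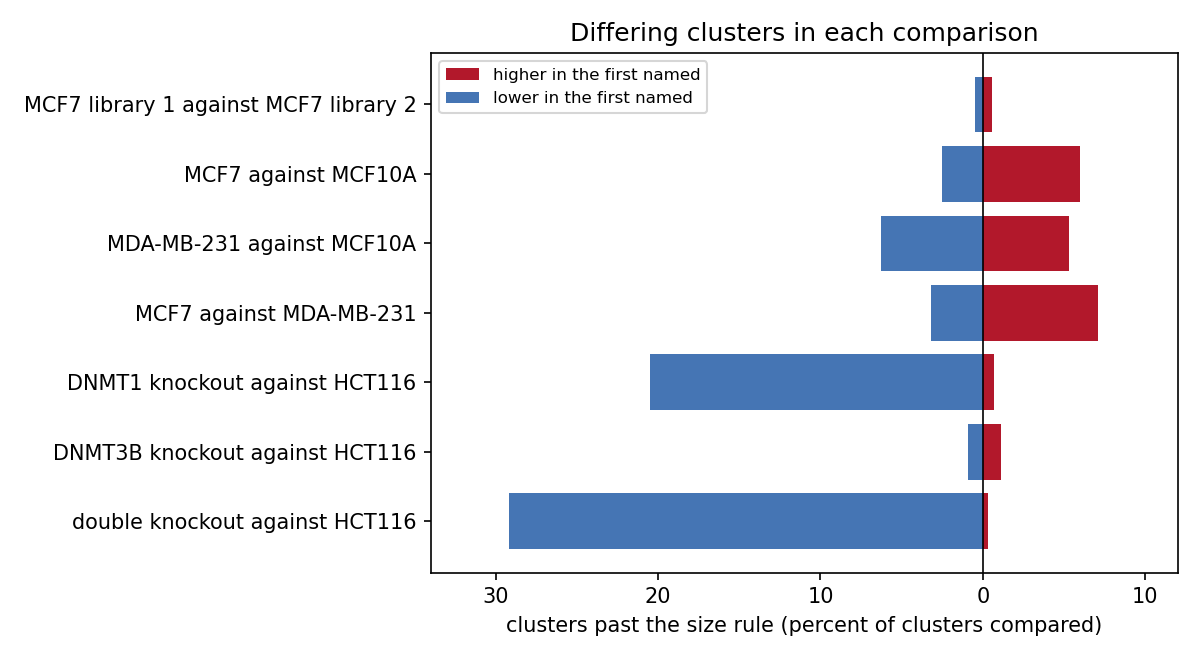
Percent of compared clusters (horizontal axis, increasing to either side of 0) that passed the size rule as higher (right) or lower (left) in the first-named library or line, for each comparison (vertical axis). The MCF7 pair passes at 0.542% and 0.459%, the double knockout at 0.319% higher and 29.2% lower. MCF7 against another line needs both MCF7 libraries to pass, a stricter rule than for lines with 1 library, so these shares are not directly comparable.

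Chromosome X differed from the autosomes in MCF10A and MCF7, and less in MDA-MB-231. Of 531 X-linked clusters, 64.2% were between 20 and 80% in MCF10A, against 30.4% of 18543 autosomal clusters. The same share on X was 35.4% and 33.9% in the MCF7 libraries and 28.6% in MDA-MB-231, and their autosomal shares were 28.2%, 28.3% and 31.5%. The median X-linked cluster level was 29.2% in MCF10A, 12.8% and 13.4% in the MCF7 libraries and 0.905% in MDA-MB-231. On autosomes the medians were 1.89% in MCF10A, 1.41% and 1.30% in the MCF7 libraries and 1.70% in MDA-MB-231.

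MDA-MB-231 was lower than MCF10A at 134 of 661 X-linked clusters (20.3%), against 5.90% of autosomal ones, and higher at 10. The median X-linked difference was -18.0 points, below all of 10000 lists of autosomal clusters matched on mean level, whose central 95% ran from -2.90 to -0.0558 points. MCF7 was lower than MCF10A at 43 of 603 X-linked clusters, with a median difference of -8.08 points against 0.0801 to 2.99 in matched lists. Between MCF7 and MDA-MB-231 the median X-linked difference was 7.27 points, above all matched lists, which ran from 0.0517 to 1.61. These percentiles describe the libraries and have no replicate behind them outside MCF7.

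**Figure D3:**
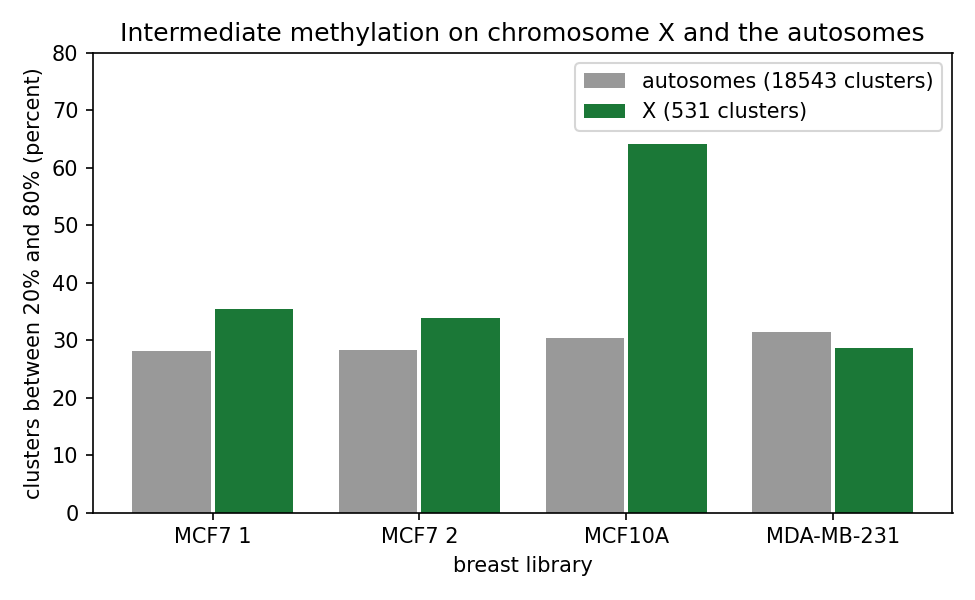
Percent of clusters between 20 and 80% methylation (vertical axis) in each breast library (horizontal axis), for 18543 autosomal and 531 X-linked clusters. MCF10A stands at 64.2% on X and 30.4% on autosomes, MDA-MB-231 at 28.6% and 31.5%.

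The DNMT1 knockout against HCT116 asks how much methylation remains in the line labelled as a knockout of the maintenance enzyme. Loss was widespread and nearly in 1 direction, with 1800 of 8779 clusters (20.5%) lower and 59 (0.672%) higher. Mean cluster methylation was 33.7% in HCT116 and 19.7% in the knockout. The 2634 clusters at 80% or over in HCT116 fell from a mean of 94.1% to 55.3%, and 20.1% of them kept a level of 80% or over. Intermediate clusters lost as well, with 334 of 758 lower.

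In the DNMT1 knockout, complete loss was read at 12 CpGs on chromosome 12, positions 52619098 to 52619281. There HCT116 stood at 100% with 209 reads per CpG and the knockout at 0% with 60.9. Complete loss was also read on chromosome 2, positions 104850708 to 104850843, and on chromosome 1, positions 53081555 to 53081716. On chromosome 20, positions 46447027 to 46447187, HCT116 stood at 100% with 399 reads per CpG and the knockout at 0% with 156. Rises were 0.672% of clusters, close to the 0.542% and 0.459% that passed between the MCF7 libraries. Among them, 11 CpGs of chromosome 2, positions 208503771 to 208503919, were at 0.356% in HCT116 and 98.5% in the knockout. On chromosome 19, positions 63052952 to 63053109, 14 CpGs went from 0% to 94.8%, and on chromosome 18, positions 26876625 to 26876875, 18 CpGs went from 4.03% to 81.5%. Losses were most frequent on chromosome 18, with 56 of 182 clusters (30.8%), and least on chromosome 3 among autosomes, with 62 of 442 (14.03%). These shares run over all clusters of a chromosome, also those too low in HCT116 to be called lower. They may therefore reflect how many clusters were methylated in HCT116.

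Fisher's exact test called 6199 CpGs higher and 48303 lower of 222899 in the DNMT1 knockout, or 24.5%, and the MCF7 pair gave 12.7%. The knockout is represented by 1 library, and the labels name 2 media for the colon cells without making clear which of them each knockout had. Counts of clusters fell to 888 lower and 22 higher where only CpGs measured in all 4 colon libraries were used, which left 4785 clusters with 18.6% lower.

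The DNMT3B knockout was close to HCT116. Of 10483 clusters, 115 (1.10%) were higher and 93 (0.887%) lower, and mean levels were 32.1% and 32.4%. The 3003 clusters at 80% or over in HCT116 stood at a mean of 94.1% there and 91.5% in the knockout, where 89.6% of them remained at 80% or over. Clusters at 80% or over in 1 MCF7 library averaged 6.34 or 4.82 points less in the other, a larger fall. Those MCF7 clusters started lower, at 88.1% or 87.6%. The SD between the MCF7 libraries was 7.89 points from 80 to 95% and 3.57 points at 95% or over. The MCF7 fall may therefore overstate that of an unchanged HCT116 library. In clusters under 150 bp 3.44% were called, close to the 3.39% of the MCF7 pair, and in clusters of 300 bp or more 0.647% were called, against 0.0830%. Over all spans 1.98% were called, against 1.00% in the MCF7 pair and 0.379% and 0.331% of unchanged clusters in 2 simulations of this comparison. The simulations may understate the spread between libraries.

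Single clusters did differ from end to end in the DNMT3B knockout. On chromosome 11, 14 CpGs at positions 45333450 to 45333675 went from 95.03% at 211 reads per CpG to 0.518% at 333. On chromosome 2, positions 112373301 to 112373371, 13 CpGs went from 100% to 0.120%, and on chromosome 17, positions 24068723 to 24068784, 11 CpGs went from 99.9% to 0.0942%. Among the rises, 11 CpGs of chromosome 16, positions 30694699 to 30694759, went from 0% to 100%, and 14 CpGs of chromosome 2, positions 176680080 to 176680208, from 2.82% to 94.5%. Most of these spans were under 150 bp, the class in which the MCF7 libraries also disagreed most often. Fisher's exact test called 13304 CpGs higher and 15143 lower of 265793, or 10.7%, under the 12.7% of the MCF7 pair. At a difference of 40 points, 74 clusters were higher and 56 lower, while with clusters of at least 5 CpGs and the size rule recomputed for them from the MCF7 pair (41.1 points), an alternative chosen after seeing the data, 198 were higher and 239 lower.

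The double knockout lost more methylation than either single one. Of 10981 clusters, 3208 (29.2%) were lower than in HCT116 and 35 (0.319%) higher, and the mean cluster level was 15.3% against 35.7%. The 3509 clusters at 80% or over in HCT116 averaged 94.1% there and 40.3% in the double knockout. Of these, 2626 were called lower, 29.0% were at 20% or under and 308 (8.78%) kept a level of 80% or over. Of 988 intermediate clusters, 582 were lower and their mean went from 53.4% to 16.2%.

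Clusters emptied in the double knockout included 13 CpGs on chromosome 1, positions 177827375 to 177827534, from 100% to 0% at 131 and 55.4 reads per CpG. On chromosome 6, positions 7671841 to 7671915, 10 CpGs went from 100% to 0%, and on chromosome 12, positions 8741797 to 8741856, 17 CpGs went from 99.99% to 0.0709%. Rises were 0.319% of clusters, under the 0.542% and 0.459% that passed between the MCF7 libraries. They included the same part of chromosome 16 as in the DNMT3B knockout, with 11 CpGs at positions 30694737 to 30694786 going from 0% to 100%. A cluster of chromosome X, positions 54573090 to 54573262, rose from 0.0911% to 59.9%, and 10 CpGs of chromosome 4, positions 111763569 to 111763632, rose from 0.0303% to 100%. Of 8 X-linked clusters called higher and 32 called lower among 189, the share of rises (4.23%) exceeded that of 10792 autosomal clusters (0.250%). Chromosome 18 again had the highest share of losses, 93 of 221 clusters (42.1%), also over all its clusters and not those able to be called lower.

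Fisher's exact test called 5837 CpGs higher and 75063 lower of 270676 in the double knockout, or 29.9%. Its 1 library has no replicate check. At a difference of 40 points 14 clusters were higher, and over CpGs measured in all 4 colon libraries 1146 clusters were lower and 8 higher.

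The double knockout was then set beside the sum of the single knockouts. Over 42042 CpGs at 80% or over in HCT116 and measured in all 4 libraries, the mean was 98.9% in HCT116, 54.4% in the DNMT1 knockout, 89.99% in the DNMT3B knockout and 42.1% in the double knockout. The double knockout fell by 56.7 points and the single ones by 44.4 and 8.87, so that the double change minus the sum was -3.43 points. If the retained shares multiplied, 50.1% would remain, and 42.6% did. CpGs chosen for a high HCT116 value may fall back in a second library, which HCT116 does not have. CpGs at 80% or over in 1 MCF7 library read 16.0 or 13.8 points less in the other, more than in the DNMT3B knockout. The MCF7 libraries were shallower, with medians of 54 and 39 reads against 139 in HCT116, so their fall may overstate that of HCT116.

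Choosing CpGs on the breast lines avoids that selection. Over 1916 CpGs at 80% or over in all 4 breast libraries, an alternative chosen after seeing the data, the means were 94.0% in HCT116, 67.6% in the DNMT1 knockout, 93.8% in the DNMT3B knockout and 58.4% in the double knockout. The double change minus the sum was then -8.99 points, and an effect of the selection cannot be told apart from the change of CpGs. No test was possible with 1 library each.

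At the level of clusters, 1281 were at 80% or over in HCT116 and measured in all 4 colon libraries. Their mean was 56.3% in the DNMT1 knockout, 91.9% in the DNMT3B knockout and 43.3% in the double knockout, with SDs over clusters of 24.3, 8.96 and 26.5 points. The double knockout lay below the DNMT1 knockout at 858 of them (67.0%), and the median double change minus the sum was -9.13 points. The 108 clusters at 20% or under in the DNMT1 knockout averaged 19.1% in the double knockout, and the 262 at 80% or over averaged 60.5%. Conversely, of 2852 clusters at 5% or under in HCT116, 23 exceeded 20% in the DNMT1 knockout, 22 in the DNMT3B knockout and 18 in the double knockout.

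**Figure D4:**
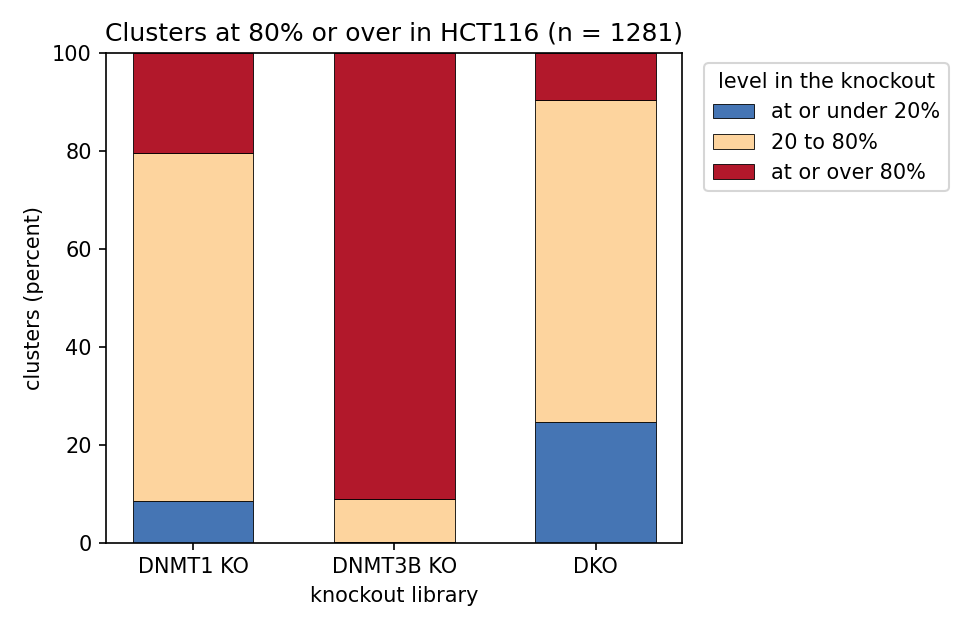
Percent of the 1281 clusters at 80% methylation or over in HCT116 (vertical axis) that lie at 20% or under, from 20 to 80%, and at 80% or over in each knockout library (horizontal axis). The class at 80% or over holds 20.5% in the DNMT1 knockout, 91.2% in the DNMT3B knockout and 9.68% in the double knockout.

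Calls were compared between the knockouts. Among 4785 clusters, 888 were lower in the DNMT1 knockout and 1146 in the double knockout, and 757 in both, against 1.43 in simulated unchanged libraries. Only the 1603 clusters at 32.2% or over in HCT116 can be called lower, and independent lists drawn within classes of 10 points of the HCT116 level would share 638, against 213 if that limit is ignored. Of the 43 clusters lower in the DNMT3B knockout, 37 were also lower in the double knockout and 28 in the DNMT1 knockout, against 28.9 and 22.96 for independent lists within classes of level and 1.44 and 1.62 in the simulation. The DNMT1 and DNMT3B knockouts shared 9 of 22 and 37 higher clusters, against 0.676 for independent lists within classes of level and 2.03 in the simulation. The double knockout shared 1 of its 8 higher clusters with the DNMT1 knockout and 1 with the DNMT3B knockout, against 0.0886 and 0.212 for such lists and 2.20 and 2.28 in the simulation. All of these share the HCT116 library, which could not be split, so part of the excess may come from it.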

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

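The tests of conversion, of nuclear copies, of a failure limited to mitochondrial DNA and of the loss of DNMT1 were chosen after the mitochondrial levels had been seen, and the test of a few amplified molecules before its result. Mitochondrial CpGs stood outside the comparisons and were flagged because the knockout libraries read above HCT116. The mean level over mitochondrial CpGs was 34.6% in the DNMT1 knockout (359 CpGs, median coverage 427 reads) and 33.1% in the double knockout (348 CpGs, 313 reads). It was 6.20% in the DNMT3B knockout and 2.79% in HCT116. In the breast lines it was 1.43% ± 0.744 (SD, n = 2) in MCF7, 6.495% in MCF10A and 1.23% in MDA-MB-231. The DNMT3B knockout thus lay under MCF10A and above the other lines not labelled as knockouts. The ratio of mitochondrial to nuclear coverage was 22.1 in MCF10A and 2.75 to 3.76 in the other libraries. The share of methylated mitochondrial reads was 34.7% (95% Wilson interval 34.5 to 34.9) in the DNMT1 knockout and 27.9% (27.7 to 28.2) in the double knockout, against 2.72% (2.64 to 2.81) in HCT116.

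Poor bisulfite conversion of the whole library would raise unmethylated nuclear clusters too. Clusters at 5% or under in all breast libraries had medians of 0.267% in the DNMT1 knockout and 0.608% in the double knockout. The medians were 0.174% in HCT116 and 0.159% in the DNMT3B knockout, so the libraries with high mitochondrial levels read slightly higher. Medians this far under the mitochondrial levels argue against poor conversion of the whole library as the source. Methylated nuclear copies of mitochondrial DNA would need mitochondrial reads to become scarce, and mitochondrial relative to nuclear coverage was 0.941 of its HCT116 value or more. A few amplified molecules would affect a few stretches, and all 17 bins of 1 kb exceeded 10% in both libraries. A bin averages several CpGs, so a few highly methylated ones can lift it over 10%. CpGs at 80% or over made up 18.4% in the DNMT1 knockout and 15.5% in the double knockout. In both libraries more CpGs lay at 20% or under, so a few amplified molecules are left undecided. Conversion failure limited to the circular mitochondrial DNA remains a candidate explanation, because the tables hold CpGs alone and the level correlated across 321 shared CpGs at r = 0.372, a value either account allows. Loss of DNMT1, with a gap of 26.7 points between the lower of these libraries and the highest other one, cannot be told apart from handling shared by these 2 libraries.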

How the results depend on the processing

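No paired analysis was possible because MCF7 is the only group with more than 1 library. A coverage minimum of 5 and windows around transcription start sites were not run. The gap of 200 bp, clusters of 5 CpGs, the effective number of reads, shared CpGs for called clusters, breast-chosen CpGs and the share of methylated reads were chosen after seeing the data. Where not stated otherwise, the cause was not tested. Of the alternative values of the main results, 158 stayed within their limit, among them all 28 under thinning and all 14 under a gap of 200 bp, and 84 moved. The limit was 1.5 times for counts and the SD of the 2 libraries for the MCF7 mean level. For other mean levels it was counting error over reads, and for knockout levels counting error over CpGs taken as independent. These last limits cover no spread between libraries. The mean of the DNMT1 knockout therefore counts as moved on autosomes only, at 34.09% against 34.14%. All 206 alternative values of named clusters kept their direction and passed the size rule. These clusters were picked for the largest differences in the same data, so that outcome was largely fixed in advance. Spans that a setting left with under 5 CpGs were not evaluated, among them several at a coverage minimum of 20. Of 98 alternative pairs of higher and lower counts, the side with more calls changed in 3, all for clusters in the DNMT3B knockout, among them summed reads with 123 higher and 125 lower under a size rule that also moved, to 35.7 points. The size rule was recomputed from the MCF7 pair for a coverage minimum of 20, thinning, autosomes only, summed reads, a gap of 200 bp and 5 CpGs per cluster, except for the pair's own counts, and its part in a change was not tested. Thinning and a coverage minimum of 20 left all counts of clusters and CpGs within 1.5 times.

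With an effective number of reads, 0 CpGs were higher and 0 lower in all 7 comparisons, which is fixed by the setting, since about 4.08 reads cannot reach an adjusted p of 0.05.

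A difference of 40 points is stricter by construction. It left 43 clusters higher and 39 lower in the MCF7 pair, with 25634 CpGs higher and 22448 lower. Against MCF10A, 342 clusters and 18151 CpGs were lower in MCF7, and 964 clusters were lower in MDA-MB-231. It left 74 clusters higher and 56 lower in the DNMT3B knockout and 14 higher in the double knockout.

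Requiring only 1 MCF7 library is looser by construction. Against MCF10A, 1976 to 1977 clusters and 80767 to 82708 CpGs were higher, and 50853 to 53824 CpGs lower. Against MDA-MB-231, 2335 to 2364 clusters and 89137 to 90564 CpGs were higher, and 42876 to 46115 CpGs lower.

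Levels from summed reads gave 202 higher and 163 lower clusters in the MCF7 pair at the size rule of 32.2 points. With at least 5 CpGs per cluster more clusters were compared, and 361 were higher and 326 lower in the MCF7 pair at 32.2 points. At a recomputed size rule of 41.1 points the counts were 112 and 3176 in the DNMT1 knockout, 198 and 239 in the DNMT3B knockout, and 61 and 5394 in the double knockout. Over CpGs in all 4 colon libraries fewer were compared, and 22 were higher and 888 lower in the DNMT1 knockout, 37 and 43 in the DNMT3B knockout, and 8 and 1146 in the double knockout.

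Mean levels depend on which CpGs enter. With a coverage minimum of 20 they were 32.1% in MCF7, 29.2% in MCF10A, 27.9% in MDA-MB-231, 40.8% in HCT116, 40.1% in the DNMT3B knockout and 29.5% in the double knockout. Over CpGs shared within a tissue they were 25.7%, 23.1% and 21.1% in MCF7, MCF10A and MDA-MB-231, and 36.1%, 21.2%, 35.4% and 16.8% in HCT116 and the DNMT1, DNMT3B and double knockouts. On autosomes only they were 32.8% in MCF10A, 30.1% in MDA-MB-231, 41.0% in HCT116, 34.1% in the DNMT1 knockout, 40.5% in the DNMT3B knockout and 29.5% in the double knockout. As shares of methylated reads they were 23.7% in MCF7, 23.8% in MCF10A, 20.01% in MDA-MB-231, 39.2% in HCT116 and 32.2%, 37.3% and 26.7% in the DNMT1, DNMT3B and double knockouts, so MCF7 was no longer above MCF10A.

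Over CpGs at 90% or more in HCT116 the means were 54.9% in the DNMT1 knockout and 90.6% in the DNMT3B knockout. Over CpGs methylated in all breast libraries they were 67.6%, 93.8% and 58.4% in the DNMT1, DNMT3B and double knockouts, with the double change minus the sum at -8.99 points.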

Other observations

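The tests of conversion, of breast-line DNA and of the loss of both enzymes on chromosome X, and that of dependence on both enzymes together, were chosen after their results had been seen, and the others in this part before. The windows with the highest shares of called clusters are given as values, without a test of local concentration. Among windows of 1000000 bp with at least 8 clusters, 28 of 30 clusters on chromosome 8, positions 1000001 to 2000000, were lower in the double knockout than in HCT116, as were all 8 in the first window of chromosome 18 and 9 of 10 on chromosome 19, positions 58000001 to 59000000. In the DNMT1 knockout, 8 of 9 clusters on chromosome 6, positions 168000001 to 169000000, were lower. On chromosome 10, positions 8000001 to 9000000, 9 of 10 clusters were lower in MCF7 than in MDA-MB-231 and 7 of 12 were higher in MDA-MB-231 than in MCF10A. On chromosome 22, positions 47000001 to 48000000, 8 of 11 clusters were higher in MCF7 than in MDA-MB-231 and 9 of 15 were lower in MDA-MB-231 than in MCF10A. On chromosome 16, positions 44000001 to 45000000, 7 of 10 clusters were lower in MCF7 and 5 of 8 lower in MDA-MB-231, each against MCF10A. These windows were the highest of 301 to 1067 per comparison and were picked for it. Their shares run over all clusters of a window, whether or not the starting level allowed a call.

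Among clusters at 80% or over in HCT116, residual methylation in the double knockout fell with CpG density. The mean was 44.7% over 712 clusters in the lowest quintile of density, 3.01 to 6.25 CpGs per 100 bp, and 34.4% over 702 clusters in the highest, 10.1 to 29.4, with SDs over clusters of 25.5 and 29.0 points. In the DNMT1 knockout the means were 56.7% and 52.6%, and in the DNMT3B knockout 90.8% and 91.5%.

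Clusters high in HCT116 and low in the breast libraries had lower levels in the double knockout than those high in both. In the double knockout, 147 clusters at 80% or over in HCT116 and at 20% or under in all breast libraries had a mean of 17.3% (SD over clusters 18.5), and 46 clusters at 80% or over in HCT116 and in all breast libraries had a mean of 63.7% (SD 20.7), a gap of 46.5 points, part of which was already there in the absence of DNMT1 alone, with 41.9% over 107 and 69.4% over 30 such clusters in the DNMT1 knockout. In the double knockout the gap was 47.4 points within quintiles of CpG density and 45.1 points within classes of the HCT116 level, which argues against density and starting level, and among clusters also at 80% or over in the DNMT3B knockout it was 38.4 points, against 37.1 without that condition, which argues against clusters that were high in HCT116 by chance. Over clusters measured in all 8 libraries, the double change minus the sum of the single changes was -22.6 points in 59 HCT116-only clusters and -6.61 points in 14 common ones, a difference of -16.0 points (bootstrap 95% interval over clusters -28.5 to -3.33), which largely restates the levels above and covers no spread between libraries of a genotype. Dependence on both enzymes together therefore cannot be told apart from a change peculiar to 1 derivative, and because the breast and colon files differed in layout, upstream processing may have shaped which clusters count as HCT116-only.

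Unmethylated clusters of chromosome X gained low-level methylation in the double knockout. Of 114 X-linked clusters at 5% or under in HCT116, 45 (39.5%) exceeded 5% in the double knockout, with a median rise of 1.35 points, against 4.47% of 5795 autosomal clusters, which argues against incomplete conversion of the library. Clusters unmethylated in HCT116 and methylated in a breast library rose by a median of at most 0.570 points. These were 17 and 26 clusters for the MCF7 libraries, 8 for MDA-MB-231 and 4 for MCF10A. The test set these medians against the upper quartile of the X-linked rise, 9.53 points, and not against its median of 1.35 points. It therefore argues against DNA of MCF7 or MDA-MB-231 for the larger X-linked rises only. For the smaller rises, and for MCF10A with 4 clusters, it cannot decide. The X-linked median rise lay above the central 95% of autosomal lists matched on the mean level of both libraries, up to 0.572 points. The lists were not matched on coverage or on molecules per cluster, so the scatter of few molecules is left undecided. Over 41 X-linked clusters in all 4 colon libraries the median rise was 4.41 points in the double knockout and at most 0.103 points in a single one. Loss of both enzymes may account for it. Few molecules, a change peculiar to this derivative, or DNA of another line, cannot be told apart from that loss with 1 library.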
